A study of Caenorhabditis elegans with 2 samples.

How the data were processed

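Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Caenorhabditis elegans embryos at the midembryo stage (3 hours, synchronised by bleaching to release eggs). The embryos carried a TY1, EGFP and 3xFLAG tag inserted by CRISPR into the endogenous ref-1 gene on chromosome II (strain RW12224), and the precipitation used an antibody against GFP, per the labels. DNA was sheared by sonication to 200 to 800 bp, per the labels. The labels give 1 group of 2 biological replicates, so there was no contrast between groups. The possible control library that the labels name was not analysed here.

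The deposited files are lists of peaks on the ce11 assembly, made by the authors from filtered alignments of the replicates and a control file, per the file headers and the accompanying notes. The aligner, the peak caller and the depth of each library are not given in the sources used here, so depth is unknown and no interval that needs it is printed. For each replicate there was a ranked list of candidate peaks and a thresholded set, and for the pair there were 2 ranked lists and 2 thresholded sets. Peaks were ranked by the irreproducible discovery rate (IDR), a measure of how reproducibly peaks rank in 2 inputs. Which 2 inputs went into the lists of a single replicate is not given in the sources used here. The score deposited with each peak equalled, in the ranked lists, a log transform of the global IDR limited to 1000, and every peak of the thresholded sets had a score of at least 830, which corresponds to a global IDR of at most 0.01. The deposited ranked lists also hold the −log10 of the global IDR. The signal deposited for each peak is the authors' own value on a scale that is not stated. It was used to describe and rank peaks within a list. In the ranked list between replicates, the deposited signal of each of the 2 inputs was read as that of the replicates, without a number for either. The authors' thresholding also used a file whose content is not stated in the accompanying notes.

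The conservative thresholded set was the main set. Gene models were those of Ensembl release 115 on the same assembly (WBcel235), with 19973 protein-coding, 612 tRNA, 346 snoRNA and 129 snRNA genes on the 6 nuclear chromosomes. The amino acid of each tRNA gene was taken from the RefSeq annotation. The promoter window reached from 1000 bp upstream to 200 bp downstream of the start of a protein-coding transcript. The position of a peak was its summit. Location was compared with 1000 random placements of the summits on the same chromosomes. The smallest p that these placements can give is 0.001. Replicates were compared by an overlap of at least 1 bp against 1000 random placements. Peak numbers on X and autosomes were compared by a two-sided exact binomial test on chromosome length.

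For sequence, the 100 bp on either side of each summit were compared with 2 windows of the same size centred 500 bp to each side, by Fisher's exact test (two-sided), for 18 motifs and for all 6-mers. Strength was compared between the 168 strongest and the 168 weakest peaks by signal for 4 motifs. For 16 gene lists, members with a summit in the promoter window were compared with all other protein-coding genes by Fisher's exact test (two-sided). P-values were adjusted by the Benjamini-Hochberg method within each family, and adjusted p-values under 0.05 were taken as past the threshold. Peaks are not replicates, so each p-value describes these 2 libraries. Intervals are exact 95% binomial (Clopper-Pearson) or conditional 95% intervals of an odds ratio, and cover counting error only.

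The sets, tests, lists, motifs and most alternatives were fixed before the data were examined. The genes named are those of the 15 strongest main peaks (promoter window, otherwise the nearest transcript start within 5000 bp). To these were added the state of each REF-1 family member, up to 4 members with the strongest peaks from each other list, and the 3 genes with the most summits from 5000 bp upstream to the gene end, with ties ordered by summed signal. The counts at tRNA, snoRNA and snRNA genes (within 100 bp), the tandem repeat measure, the GC-matched windows and the peaks left out on that basis were chosen after seeing the data. A summit was placed on a tandem repeat where at least 75% of the bases of its window matched themselves at one shift of 8 to 100 bp. GC-matched windows were 5 per peak, from the same chromosome, within 2 percentage points of GC content. They were drawn without regard to gene position, so their share in exons was not matched to that of the summits. Alternatives comprised the other thresholded set, stricter thresholds, each replicate's own set, other windows, backgrounds and overlap rules. The threshold planned as stricter, a global IDR of at most 0.01, turned out to be the authors' own and removed no peak, so 0.001 was added.

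The functions were tested on simulated data. With 700 random peaks, 0 of 18 motifs, 0 of 2080 6-mers and 0 of 16 gene lists passed the threshold. With 30% of peaks planted at tRNA genes, 30.3% were found there. With CACGTG planted at 30% of summits, it ranked 1 among the 2080 6-mers. With peaks planted at 40 of the 81 ribosomal protein genes, 43 members were found bound, chance peaks and shared windows included. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.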

Results

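The data describe where tagged REF-1 was found on the genome of midembryos. REF-1 is the founding member of a nematode family of HES-related proteins with 2 basic helix-loop-helix domains, and several family genes are known targets of Notch signalling in the early embryo. The samples were 2 biological replicates of whole embryos of 1 strain, and the antibody recognised the GFP tag. The conservative set held 675 peaks, most of them (570) 276 bp wide. Some of these intervals overlapped one another, and merging them left 651. Several of the weakest entries carried the same pair of replicate signals as a stronger entry. The authors' signal had a median of 102.3 in this set, with quartiles of 81.6 and 166.2. The other thresholded set of the pair held 653 peaks, of which 554 overlapped the conservative set. The ranked list behind the conservative set held 72151 candidates. The depth of the libraries is unknown.

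Most peaks of each replicate overlapped a peak of the other. Replicate 1 had 344 peaks of its own and replicate 2 had 405, and 265 peaks of replicate 1 (77.0%) overlapped a peak of replicate 2, as did 265 of replicate 2 (65.4%) with replicate 1. Random placement gave a mean of 0.652 and at most 4 shared peaks in 1000 placements (one-sided permutation p = 0.001, the smallest they can give). Peaks are not independent replicates, and the conservative set was selected for reproducible rank. Of the 675 peaks, 267 overlapped the own sets of both replicates and 260 overlapped neither. The median signal of the former was 187.0 and that of the latter 80.0.

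**Figure D1:**
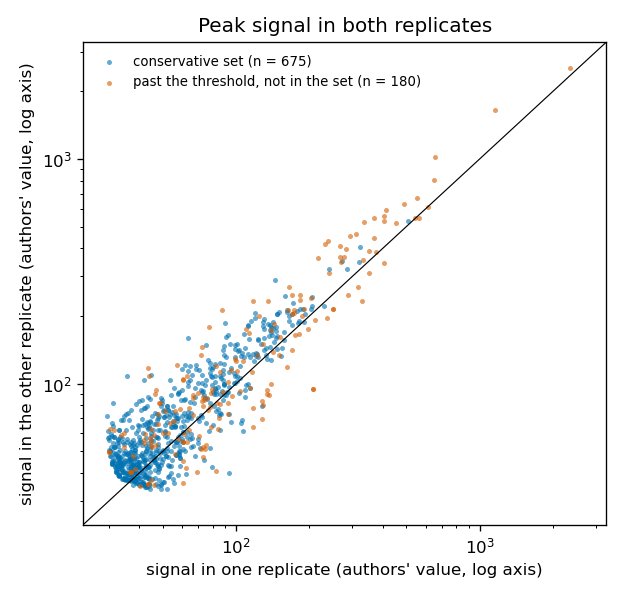
Signal of each peak in the one replicate (x axis) and the other (y axis), both the authors' values on log axes, for the 675 peaks of the conservative set and for 180 peaks that passed the same threshold in the ranked list but are not in the set. The line marks equal signal, and the point farthest from the origin, at 2348 and 2540, is 1 of the 180 other peaks.

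Genes for tRNAs, snoRNAs and snRNAs, small structured RNAs, held 279 of the 675 summits (41.3%). Of these summits, 218 (32.3%, exact 95% interval 28.8% to 35.97%) lay within 100 bp of a tRNA gene, 50 (7.41%) within 100 bp of a snoRNA gene and 11 (1.63%) within 100 bp of a snRNA gene. Random placement gave means of 0.185%, 0.114% and 0.0361%, and none of the 1000 placements reached the observed value for any of the 3 classes (one-sided permutation p = 0.001 each, the smallest they can give). Among the 100 strongest peaks, 48 were at tRNA genes and 29 at snoRNA genes. The median signal was 261.4 at snoRNA genes, 144.0 at tRNA genes, 108.2 at snRNA genes and 90.3 at promoters outside these classes. The tRNA share was 45.1% in the own set of replicate 1 and 39.5% in that of replicate 2. This location was chosen for counting after the strongest peaks had been seen. With a global IDR of at most 0.001 the share rose to 52.4%.

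Counted by gene, 221 of 612 tRNA genes (36.1%, interval 32.3% to 40.1%) had a summit within 100 bp, against 51 of 346 snoRNA genes (14.7%) and 11 of 129 snRNA genes (8.53%). The summits at tRNA genes sat at a median of 21 bp (quartiles 9.25 and 34.8) downstream of the 5′ end of the gene, and 193 of the 218 lay inside the gene. The bound genes covered all 20 standard amino acids, with shares from 21.1% of 19 tyrosine genes to 53.8% of 13 cysteine genes. The selenocysteine gene and 5 genes with no amino acid given had no summit. None of the 22 groups passed the threshold (Fisher's exact test, two-sided, lowest unadjusted p = 0.165, lowest adjusted p = 0.988). The strongest tRNA peak, with a signal of 401.3, lay over the tRNA-Asn gene WBGene00023042 (X, 8404499 to 8404571) in an intron of sulp-3. A single-sequence tRNA-Leu gene, WBGene00000308 (X, 13665555 to 13665673), had a peak of 395.0. The RNA gene of RNase P, rpr-1 (I, 13463955 to 13464207), which serves in tRNA maturation, had a peak of 245.7. The 20 annotated rRNA genes, 5S genes included, had no peak in the conservative set. Among snRNA genes, 3 of the 14 that share the name R07E5.16 and the SL2 RNA genes sls-2.2 and sls-2.4 had peaks. The genes of this paragraph were chosen after their values were seen. Reads from near-identical tRNA, snRNA and rRNA copies cannot be assigned with certainty, so the values of single copies are uncertain and a peak at an rRNA gene may not have been detectable.

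**Figure D2:**
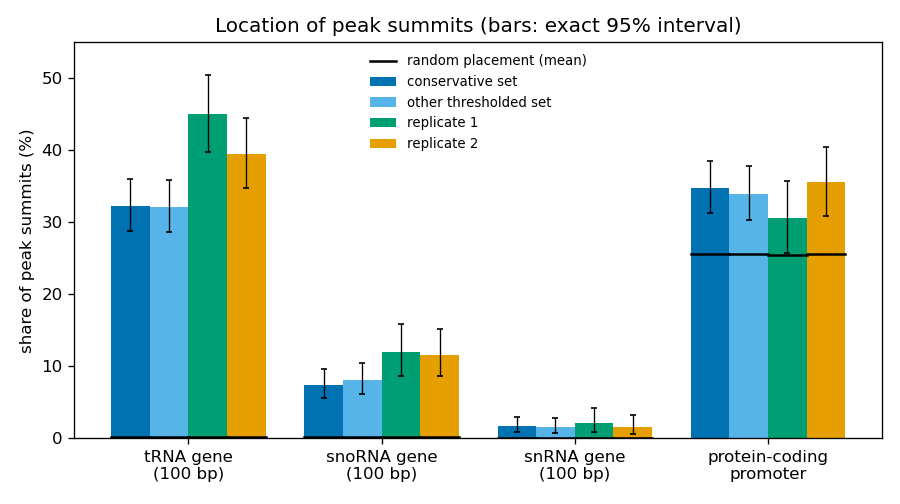
Share of peak summits (y axis, percent) within 100 bp of tRNA, snoRNA and snRNA genes and in protein-coding promoters (x axis), for the conservative set, the other thresholded set and the own set of each replicate. Bars are shares with exact 95% intervals and black lines are means of 1000 random placements. The tRNA share was 32.3% in the conservative set and 0.185% under random placement.

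The strongest peak of the set (V, 12303493 to 12303780, signal 1045.3) lay at the snoRNA genes C51F7.3 and C51F7.4 inside an intron of frm-7, with F55C5.17 as the nearest protein-coding start at 1100 bp. The next (I, 8259437 to 8259699, signal 729.7) covered the snoRNA gene ZK265.10 in the promoter window of sre-23, a gene of the serpentine chemoreceptor class. The peak at V, 15873851 to 15874126 (signal 676.0), lay at the snoRNA gene T06C12.16, 1404 bp from the start of str-56, another chemoreceptor gene. The peak in the promoter window of K12H4.5 (III, 8043852 to 8044069, signal 624.9) was the strongest away from all 3 RNA classes. Of the 15 strongest peaks, the others at snoRNA genes had W03C9.1, cutl-18, Y43F8C.7 and M106.8 as nearest starts within 5000 bp, and 1 in an intron of the peroxidasin gene pxn-1 had none. Those at tRNA genes were assigned to sulp-3, nlp-76 and F28H6.7. The remaining 3 were intergenic near hrg-5, at the microRNA gene mir-51 (signal 458.8), intronic in cmk-1 with ccm-2 as the nearest start (456.6), and intergenic near C04G6.6 on a tandem repeat (441.5).

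Promoters of protein-coding genes held 34.8% of the 675 summits (exact 95% interval 31.2% to 38.5%), against 25.6% ± 1.68 (SD over 1000 placements) at random (one-sided permutation p = 0.001, the smallest they can give). Away from tRNA, snoRNA and snRNA genes the share was 41.9% of 396 summits, against 26.04% at random. Exons of protein-coding genes held 6.52% of summits against 29.3% at random, and introns held 37.6% against 33.6%. The remaining 55.9% lay outside protein-coding genes, against 37.1% at random. Away from tRNA, snoRNA and snRNA genes the direction turned for introns, with 29.3% against 33.9% at random (one-sided permutation p for fewer = 0.031). The higher intron share of the whole set therefore came with these genes. The promoter windows assigned the peaks to 284 of 19973 protein-coding genes, and for 77 of these each assigned summit was at a tRNA, snoRNA or snRNA gene. With a window of 2000 and 500 bp the share was 52.1%, and with 500 and 100 bp it was 24.7%.

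None of the 6 members of the REF-1 family had a peak in any of the 4 thresholded sets. At ref-1 itself (II, 10218471 to 10220022), the gene that carried the tag, the strongest candidate of the ranked list (II, 10219601 to 10219876) had a signal of 52.3 and ranked 4419 of 72151, with a score of 318 against the 830 at the threshold. The nearest peak of the conservative set was 27728 bp away. The genes hlh-25, hlh-26, hlh-27, hlh-28 and hlh-29 had no candidate at all in the gene or promoter window in any of the 4 ranked lists. Only 20.6% of the 36-mers at hlh-28 and 20.9% at hlh-29 occur once in the genome, against 53.0% at hlh-25, 52.4% at hlh-27 and 100% at hlh-26 and ref-1. A peak at hlh-28 or hlh-29 was therefore hardly detectable if reads with several positions were left out, and whether they were is not given in the sources used here.

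Lists of developmental regulators were compared with all other protein-coding genes. None of 22 Notch pathway genes, 32 other helix-loop-helix factors, 6 Hox genes, 9 endoderm, 11 pharynx, 10 muscle and mesoderm or 31 neuron factors had a summit in the promoter window. With 1.42% of all protein-coding genes bound, lists of this size hold fewer than 1 bound member by chance, so a lower share was not detectable (Fisher's exact test, unadjusted and adjusted p = 1.00 for each of these lists and for the REF-1 family). The upper 95% bound of the odds ratio was 12.7 for the Notch list and 8.51 for the other helix-loop-helix factors. When each summit went to the nearest start within 5000 bp, the Notch (odds ratio 3.44), pharynx (3.43), neuron (1.14) and other helix-loop-helix (1.11) lists had bound members, as had the Notch list with the window of 2000 and 500 bp (2.06), and none of them passed. Of the epidermis factors 1 of 11 was bound, the T-box gene tbx-8, with a summit in its 5′ UTR (III, 10347270 to 10347545, signal 71.3, Fisher's exact test of the list, adjusted p = 0.583). Of 25 Wnt pathway genes 1 was bound, the porcupine homologue mom-1 (X, 6292246 to 6292426, signal 353.2, Fisher's exact test of the list, adjusted p = 0.964), and that summit lay at a tRNA gene. Of genes for late or other tissues, 1 of 156 collagens (col-185, signal 140.5, also at a tRNA gene, Fisher's exact test, adjusted p = 1.00), 0 of 31 major sperm protein genes and 0 of 6 vitellogenin genes (adjusted p = 1.00 for both) had a summit.

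Ribosomal protein and histone genes were bound more often than other protein-coding genes. Of 81 cytosolic ribosomal protein genes 6 (7.41%) were bound, against 1.40% of other genes (odds ratio 5.64, 95% interval 1.99 to 13.0, Fisher's exact test, adjusted p = 0.00834). The strongest were rpl-3 (III, 3867449 to 3867724, signal 150.4), rpl-15 (IV, 654807 to 655082, signal 134.4), rpl-35 (III, 7854554 to 7854829, signal 123.8) and rps-28 (IV, 1659091 to 1659366, signal 100.3). Of 50 core histone genes 5 (10%) were bound (odds ratio 7.82, interval 2.40 to 19.8, Fisher's exact test, adjusted p = 0.00834). These 5 genes rest on 3 entries of the set. The promoters of his-61 with his-62 (signal 85.9) and of his-3 with his-4 (signal 70.2) were shared. The other entry, in the window of his-41, had a deposited signal of only 6.39, and this gene was named after its value was seen. Several of the weakest entries repeat the replicate signals of a stronger entry, and whether this one does was not examined. Among 25 heat-shock and chaperone genes the divergent pair F44E5.4 and F44E5.5, inducible HSP70 genes, shared 1 peak (II, 11759337 to 11759612, signal 102.6), and the list was not past the threshold (Fisher's exact test, adjusted p = 0.260), although it passed in the other thresholded set (odds ratio 9.61, adjusted p = 0.0309). Both calls rest on few genes. In the own set of replicate 1 no histone gene was bound and the ribosomal list passed (Fisher's exact test, adjusted p = 0.0301), and in that of replicate 2 neither passed (odds ratio 4.16 and adjusted p = 0.210 for ribosomal proteins, 6.92 and 0.178 for histones). Neither passed when each summit went to the nearest start within 5000 bp (Fisher's exact test, adjusted p = 0.438 and 1.00).

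The most summits within a gene and its 5000 bp upstream, 4, were found at sms-3 (III, 1583155 to 1601144) and its neighbour Y22D7AL.6 (III, 1604926 to 1606851). Both had the same summed signal of 402.3, so the same 4 summits appear to have been counted for both. Of these, 1 lay at a tRNA, snoRNA or snRNA gene. The linker histone gene hil-3 (X, 8159169 to 8160084) had 3, all at such genes.

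Peaks were denser on X than on autosomes, and this came with the tRNA genes of X. There were 147 peaks on X (8.30 per Mb) and 6.40 per Mb on autosomes. The X share of 21.8% (interval 18.7% to 25.1%) exceeded the 17.7% expected from length (exact binomial test, two-sided, p = 0.00637). Of the summits on X, 93 lay at tRNA genes, and X holds 276 of the 612 tRNA genes. The share of tRNA genes bound was 33.7% on X and 38.1% on autosomes (odds ratio 0.83, interval 0.58 to 1.17, Fisher's exact test, p = 0.272). Away from tRNA, snoRNA and snRNA genes, the direction turned, with 2.99 peaks per Mb on X and 4.15 on autosomes (exact binomial test, p = 0.0249). Among autosomes, III had the highest density, 8.63 per Mb (interval 7.26 to 10.1), and V the lowest, 4.54 (3.72 to 5.46).

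**Figure D3:**
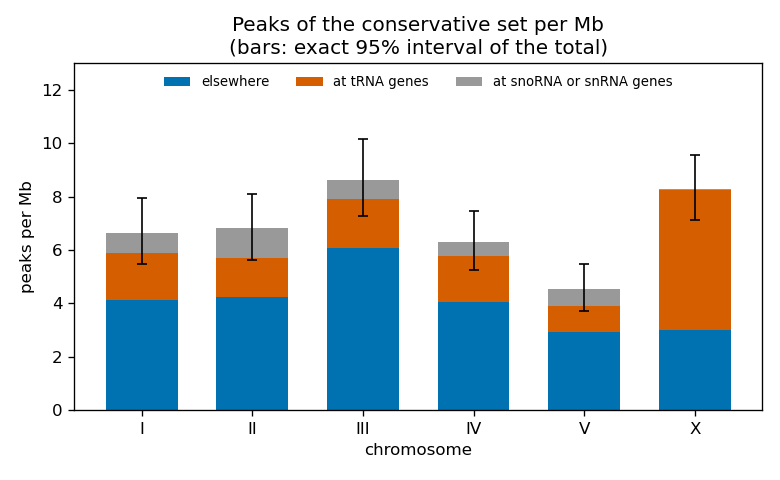
Peaks of the conservative set per Mb (y axis) on each chromosome (x axis), divided into those at tRNA genes, at snoRNA or snRNA genes and elsewhere. Error bars are exact 95% intervals of the total. X had 8.30 peaks per Mb in all and 2.99 away from these genes.

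Of the sequences bound by HES-type proteins, 3 forms were more common at summits than in the flanks, and the call of the palindromic E-box depended on the setting. The HES class C site CACGCG was present at 12.59% of 675 summits and in 1.78% of 1350 flanking windows. Its odds ratio was 7.95 (interval 4.95 to 13.2, Fisher's exact test, adjusted p = 1.76e-21). In splits made after the data were seen, it was 14.59 (5.96 to 43.03) at the 218 tRNA summits. At the 396 summits away from the 3 RNA classes it was 5.26 (2.87 to 10.01), also against flanks. CACGCG alone was not compared between bound and unbound tRNA genes. How far tRNA gene sequence raises the value over all summits is therefore unknown. The degenerate form CACGNG was at 27.6% against 12% (odds ratio 2.79, same exact test, adjusted p = 1.78e-16) and the N-box CACNAG at 31.9% against 18% (odds ratio 2.13, adjusted p = 2.45e-11). The palindromic E-box CACGTG was at 4.74% against 3.19% (odds ratio 1.51, interval 0.92 to 2.47, same exact test, adjusted p = 0.170), and it passed in the other thresholded set (1.85, adjusted p = 0.0250), within 50 bp of summits (2.13, adjusted p = 0.0369) and against random transcript starts (1.74, adjusted p = 0.0210). The control palindrome GCATGC passed in the other thresholded set too (2.13, same exact test, adjusted p = 0.0278), as it did in the own set of replicate 2 (4.93), among the 337 strongest peaks (2.66) and at a global IDR of at most 0.001 (3.24). The control CGTACG (4.03, interval 1.08 to 18.4) passed among the 337 strongest (10.1), with merged overlaps (5.38) and at 0.001 (10.2). Any E-box (CANNTG) was at 51.6% against 50.4% (same exact test, adjusted p = 0.857), although it passed in the other thresholded set (odds ratio 1.25, adjusted p = 0.0349). The GC box CCGCCC (12% against 3.26%) and GAGAGA (22.7% against 10.8%) were also more common, and the GATA site HGATAR (32% against 40.1%), the SKN-1 site RTCATC (10.5% against 18.3%) and TAATTA (5.19% against 9.78%) less common. The LAG-1 site RTGGGAA, through which Notch acts, was at 7.70% against 7.19% (same exact test, adjusted p = 0.857). Summit windows had a GC content of 46.1% ± 6.52 (SD, 675 windows) and flanks 36.6% ± 7.43. Against windows of equal GC content, CACGCG (odds ratio 3.01, interval 2.25 to 4.01) and CACGNG, which includes it (1.46, 1.20 to 1.77), remained past the threshold, as did GAGAGA (1.64), CCGCCC (1.68) and, lower, RTCATC (0.39). The CACGNG call came with CACGCG, since the other forms (CACGDG) were at 17.3% against 17.1% (odds ratio 1.02, 0.81 to 1.27), a split made after the values were seen. CACGTG was at 0.85 (0.56 to 1.25) against these windows, CACNAG did not pass (1.19, same exact test, adjusted p = 0.125) and CANNTG was less common (0.72, adjusted p = 0.000502). Against these windows HGATAR lost its call (0.90, same exact test, adjusted p = 0.297) and TAATTA turned to 1.59 (adjusted p = 0.0606). Away from the 3 RNA classes and against GC-matched windows, CACGNG missed the threshold (1.31, interval 1.01 to 1.70, same exact test, adjusted p = 0.0738). CACNAG there turned to less common (22.2% against 28.0%, odds ratio 0.73, interval 0.56 to 0.95, same exact test, adjusted p = 0.0475), and HGATAR was less common (0.70, adjusted p = 0.00957). Exons held 6.52% of the 675 summits against 29.3% at random, and the GC-matched windows were not matched on exons. Changes against these windows therefore cannot be assigned to GC content alone.

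**Figure D4:**
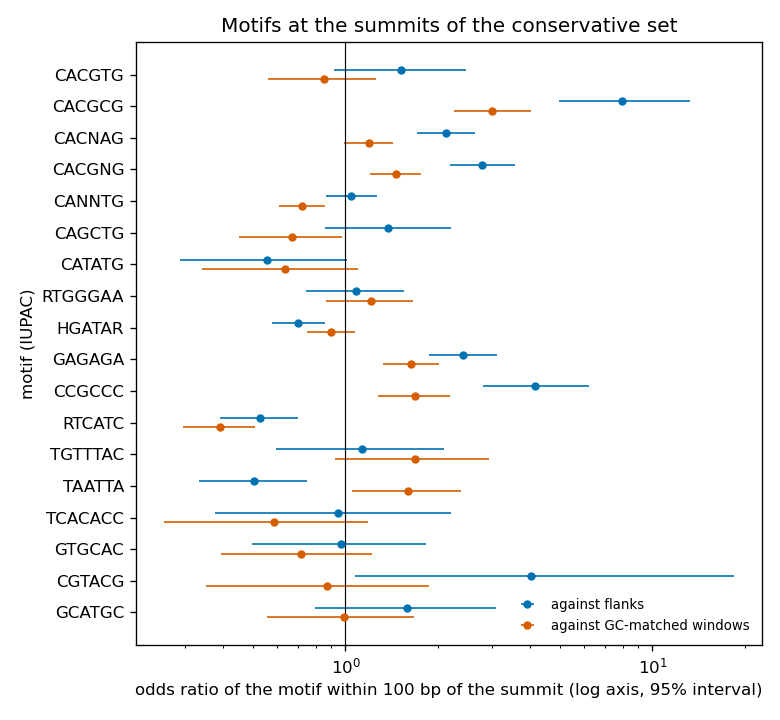
Odds ratio of each of the 18 motifs (y axis) within 100 bp of the 675 summits (x axis, log scale, with 95% intervals), against flanking windows and against windows of equal GC content. CACGCG had the ratio 7.95 against flanks and 3.01 against GC-matched windows.

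A search over all 2080 6-mers found 580 more common and 438 less common at summits past the adjusted threshold. Against GC-matched windows 324 were more common and 453 less common, and 110 and 266 when the 3 RNA classes were left out too. Ordered by p, CGAACC and GTTCGA led, and both lie within the consensus of the tRNA B box, an internal promoter element of tRNA genes. The next, GAACCC, shares only part of that consensus. CGAACC was at 28.7% of summits against 4.37% of flanks, GTTCGA at 32% against 7.56% and GAACCC at 21.9% against 4.67%. CCCCGC, ACCACT, AGAGCG, CACGCG, CGGCCA, CCACGC and CCCGGG followed, and the A and T rich AAAATT (38.4% against 62.1%), AAATTA and TTCAAA had the smallest p of those less common. The B box consensus GGTTCGANTCC with at most 1 mismatch was at 81.2% of tRNA summits, at 22.95% of snoRNA and snRNA summits and at 6.31% of the remaining 396, against 0.884% in the flanks of the last (odds ratio 7.54, interval 3.14 to 20.8). Away from the 3 RNA classes, GCGCGC (14.1% against 1.64%), CGCGCA (15.9% against 2.53%) and GCGCAC (15.2% against 2.65%) led, and CACGTG was at 6.82% against 2.65% (odds ratio 2.68, Fisher's exact test, adjusted p = 0.00329), but its call ended against GC-matched windows (6.82% against 5.35%, odds ratio 1.29, adjusted p = 0.337).

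Motif content was compared between the 168 strongest and the 168 weakest peaks. CACNAG was at 36.3% of the former and 23.2% of the latter (odds ratio 1.88, interval 1.14 to 3.13, Fisher's exact test, adjusted p = 0.0481). CACGTG (5.36% against 4.17%), CACGCG (14.3% against 8.33%) and CANNTG (55.95% against 45.8%) did not pass (same exact test, adjusted p = 0.799, 0.160 and 0.160). The CACNAG difference was lost in the own set of each replicate and turned to an odds ratio of 0.84 away from the 3 RNA classes. There CACGTG passed, at 12.1% of the 99 strongest and 2.02% of the 99 weakest (odds ratio 6.64, interval 1.42 to 62.7, same exact test, adjusted p = 0.0403). Some of the weakest entries of the conservative set repeat the replicate signals of a stronger entry. This CACGTG split was not rerun with overlapping peaks merged and was not matched on GC content, so it cannot separate strength from either.

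Peaks found in 1 replicate only were weaker and less often at tRNA genes, and these differences were not separated from one another. In replicate 1, 79 of 344 peaks had no overlap with replicate 2, with a median signal of 50.1 against 86.1 for shared peaks (two-sided Mann-Whitney permutation test, p = 1e-05, the smallest that 100000 resamples can give). In replicate 2, 140 of 405 had none, with 59.8 against 102.3 (same permutation test, p = 1e-05). The tRNA share was 31.6% against 49.1% in replicate 1 (Fisher's exact test, p = 0.00684) and 21.4% against 49.1% in replicate 2 (p = 4.1e-08). The promoter share was 27.8% against 31.3% in replicate 1 (same exact test, p = 0.581) and 43.6% against 31.3% in replicate 2 (p = 0.0164). Of the unshared peaks, 73 of 79 and 129 of 140 overlapped a candidate in the ranked list of the other replicate. Each set was cut at a score threshold, so a lower signal of unshared peaks can follow from the cut alone. In the ranked list between replicates the tRNA share was 32.2% in the first 500 candidates and 12.4% in the next 500. Shares were not matched on signal, so the lower tRNA share cannot be told apart from the lower signal.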

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

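The test of tandem repeats was chosen after the missing peaks had been seen.

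In the ranked list between replicates 855 peaks passed the threshold of the conservative set, and 180 of them (21.1%) are missing from that set. These stand outside the comparisons of where REF-1 was found, although the highest signal among them was 4694, against 1045.3 in the set, and 56 of the 100 strongest peaks past the threshold were among them. Of the 180, 138 (76.7%) lay on tandem repeats, against 48 of 675 in the set (7.11%) and 0.444% of random positions, an odds ratio of 42.5 (95% interval 26.6 to 69.3), which is consistent with a filter on repeats, where reads from many copies could pile up. None lay at a tRNA gene and 171 lay outside protein-coding genes. Whether the file of unstated content that the authors used removed them stays open, and no biological explanation was tested, since the design has 1 group.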

How the results depend on the processing

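The settings with a global IDR of at most 0.001, with merged overlaps, without tandem repeats, without peaks at tRNA, snoRNA and snRNA genes, and with GC-matched windows were chosen after the data were seen.

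Of 752 values under alternatives, 601 were taken as unchanged. For tests this meant the same direction and side of the threshold. Counts had to stay within a fixed ratio of the main count, and correlations within their interval. The shares of summits in promoters and at tRNA genes stayed above random placement in each alternative run, with tRNA shares of 32% to 52.4%. A global IDR of at most 0.01 removed no peak and tests nothing, and its values, unchanged by construction, are among the 601. With fewer peaks by construction, the set held 337 peaks when limited to the strongest by signal and 246 at a global IDR of at most 0.001. The own sets of single replicates, made from other lists, held 344 to 405. The X to autosome ratio reversed to 0.720 without tRNA, snoRNA and snRNA genes. Motifs higher at summits numbered 8 in the other thresholded set and at 0.001. The 6-mers higher numbered 249 without those genes and 324 with GC-matched windows, and those lower 245 without those genes and 288 at 0.001. Against GC-matched windows CANNTG reversed to an odds ratio of 0.72 and TAATTA to 1.59. The number of motifs that differed by strength fell from 1 to 0 in the other set, among the 337 strongest, at 0.001, with merged overlaps and without either replicate, and was 1 without those genes, through CACGTG in place of CACNAG. The odds ratio of CACNAG by strength, 1.88 in the conservative set, was 1.79 in the other set and 1.11 among the 337 strongest. It reversed to 0.82 at 0.001 and 0.84 without those genes. The gene lists past the threshold rose from 2 to 3 in the other thresholded set, and fell to 0 among the 337 strongest, at 0.001 and with the nearest start, to 1 with the window of 500 and 100 bp, and to 0 to 1 without 1 replicate. The ribosomal protein odds ratio stayed at 5.39 among the 337 strongest and 8.27 at 0.001. The core histone odds ratio was 0 among the 337 strongest peaks and at 0.001, where no member was bound. With so few peaks a lower share was not detectable, so this is not a reversal. Without 1 replicate the core histone odds ratio was 0 to 6.92. The rank correlation of the replicates' signals across all candidates, 0.22, was 0.72 in the conservative set and 0.36 as Pearson's r of log2 signals. Except for the 337 and 246 peaks, the cause was not tested. Depth is unknown, so what it limits cannot be given.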

Other observations

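The counts at other RNA classes and inside genes, the tests of sequences that occur once, of sites that include the N-box, of other transcribed genes and of a control, and those of CACGDG, and of CACGTG and CACGCG away from tRNA, snoRNA and snRNA genes were chosen after the results were seen.

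Other classes of RNA genes differed in how often they held a summit. Of 261 microRNA genes 4 had one within 100 bp, and 4 summits (0.593%) lay there against 0.0742% at random (one-sided permutation p = 0.005). Of 15363 piRNA genes 2 had one, with 0.296% of summits against 2.07% at random (one-sided permutation p for fewer = 0.001, the smallest the placements can give). The lincRNA genes were near random placement, with 0.296% against 0.281%. Pseudogenes held 1.93% against 3.29% (one-sided permutation p for fewer = 0.027). Of 7764 genes annotated as ncRNA 213 had a summit, and random placement was not computed for them. Of 291 tRNA genes inside a protein-coding gene 38.5% were bound, against 33.96% of the 321 others (odds ratio 1.22, 95% interval 0.86 to 1.72, Fisher's exact test, two-sided, p = 0.273).

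Down the ranked list, the tRNA share was lower among weaker candidates. It was 32.2% in the first 500 candidates, 12.4% in the next 500 and 0.2% in those ranked 2501 to 3000, whereas the promoter share was 23.8%, 34.8% and 29.0%.

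Reads shared between tRNA copies are a candidate explanation for the summits at tRNA genes that stays open: 0 of 25 genes whose 36-mers all occur once were bound (0%, exact upper bound 13.7%), against 37.6% of the other 587, and 10 times random placement would be under that bound. Of the 143 genes whose whole sequence occurs once, 22.4% (15.8% to 30.1%) were bound, against 0.195% under random placement and 40.3% of the others. Copies identical over the whole gene are therefore not the only cause, although copy number went with being bound. These 143 genes can still share 36-mers with near-identical copies, so the split cannot exclude shared reads. Of 473 genes with no unique 36-mer, 190 (40.2%) were bound. The split by whole sequence was picked from several tried after the first gave 0. Among these were genes with most but not all 36-mers unique (19 of 62 bound, 30.6%, 19.6% to 43.7%) and flanks of 200 bp (41.6% bound where unique, 20.6% elsewhere). For open DNA at any highly transcribed gene, tRNA genes were compared with ribosomal protein and core histone genes (36.1% against 8.40% bound, odds ratio 6.15, 3.23 to 12.9). The windows differed, with 100 bp around tRNA genes and the promoter window for the others. Open DNA was not measured and shared reads may raise the tRNA share, so this comparison cannot decide. Only 28.0% of tRNA summits (22.1% to 34.4%) held CACGTG or CACGNG, which counts against these forms as the whole cause. With the N-box included, 53.2% of tRNA summits (46.4% to 59.98%) held a site, as did 50.2% of bound and 48.3% of unbound tRNA genes (odds ratio 1.08, 0.76 to 1.52), so sites of this wider kind stay open; that any precipitation of GFP gives these summits cannot be told apart from binding of REF-1, since 0 control precipitations were analysed, and no biological explanation was tested.

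The higher share of CACGNG at summits remained past the threshold against GC-matched windows (odds ratio 1.46) and, against flanks, away from tRNA, snoRNA and snRNA genes (2.60), but with both combined it missed the threshold (1.31, 1.01 to 1.70), and this form includes CACGCG. For the other forms, CACGDG, GC content stays a candidate explanation. Their odds ratio was 1.77 against flanks and 1.02 (0.81 to 1.27) against GC-matched windows. The annotated tRNA, snoRNA and snRNA genes do not account for the difference against flanks (1.96 away from them, 1.36 to 2.82). Of the 396 summits away from them, 6.31% still held the B box consensus with at most 1 mismatch, and these were not left out. GC content stays a candidate for CACGTG away from those genes too, with 2.68 against flanks and 1.29 (0.80 to 2.02) against GC-matched windows. These tests were first written for CACGNG and CACGTG together and parted after the results. For CACGCG there (2.78, 1.82 to 4.18), the 11 other 6-mers with the same bases and 2 CpG pairs had a median odds ratio of 0.943, which counts against base content in general, although CGCACG (3.60) and CGCGCA (3.34) were above CACGCG and ACGCGC (2.59, 1.73 to 3.83) was close to it. Direct binding to CACGCG may therefore be 1 of several sources, and no test here tells it from binding to CpG-rich DNA of another order.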
